A study of Mus musculus with 12 samples.

How the data were processed

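Class-switched B cells were sorted from Peyer's patches, the lymphoid follicles of the small intestine, of wild type Taconic mice without or with segmented filamentous bacteria (SFB), a gut commensal. IgA, IgG1 and IgG2b cells were sorted one isotype at a time and, per the labels, mixed back in the ratio found in the tissue. Cells of 5 mice were pooled per group, and each pool was loaded in 2 wells. Each of the 4 wells gave a 5' gene expression library, a surface antibody library and a B cell receptor library.

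The deposited matrices held counts of unique molecular identifiers (UMIs) per gene or antibody and barcode, written by Cell Ranger 7.0.0 per the file headers. The submitters' processing notes also named Seurat and the GRCm38 and mm10 builds, without versions. The contig tables the authors annotated, with dandelion in their names, held the fraction of V bases equal to the germline V gene, and UMI counts per contig. The deposited annotation per cell, of other units, gave the kept cells, clusters, predicted cell types, isotype, clone and a mutation count. The filters behind the kept cells and the way the cell types were predicted were not given in the sources used here. The matrices held 60805 barcodes, 32285 genes, 7 antibodies and 3 hash features, and the authors kept 25826 cells, which were used as they stand.

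Files were checked against each other. Gene UMI totals equalled the annotation in 76.2% of cells, and the largest difference was 1.51%. The isotype of the heavy chain contig with most UMIs equalled the annotated isotype in 99.98% of cells. All kept cells had a productive heavy chain contig in the authors' tables, but in the filtered table of Cell Ranger 3978 of them (15.4%) had no productive one and 73 had 2. A count of 647 cells (2.51%) held 2 or more productive heavy chain contigs. Scrublet marked only 2 cells as doublets, too few to act as an alternative, so that the planned doublet alternative rests on the cells with 2 or more heavy chains. Whether Scrublet's scores rank doublets well in these cells was not tested.

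The cell types GCB, FOB and PB are the authors' predictions and are read here as germinal centre B cells, follicular B cells and plasmablasts. Within them the authors' clusters are given by number, since no marker list named them without overlap. Cluster 2 was led by Sell, Rasgef1b and Plaur. Cluster 3 was led by Ccr1, Fabp6, Fcrl5, Plac8, Cfp, Tbc1d9 and Bhlhe41, and held 13 of 14 atypical memory markers and 12 memory markers above detection. Fcrl5 and Bhlhe41 are atypical memory markers, and no memory marker was among its leading genes. Detection alone does not set it apart, since 11 germinal centre and 10 cycling markers were also detected there. Cluster 2 likewise held 12 memory markers above detection. Cluster 5 was led by Prg2, Ly6c2, Fkbp11, Atp1b1, Ccr10 and Jchain.

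A group was 1 sample, so that no test was possible and no p-value or standard error is given. Shares of cells and clones carry exact Clopper-Pearson 95% intervals, and ratios of summed UMIs carry exact Poisson 95% intervals. Both cover counting error only, and none covers the difference between mice. The Poisson intervals also leave out variation between cells, although the UMIs of a gene can gather in few cells, as for Prg2 in PB. Values per well show the technical spread, and no replicate check of a group difference exists.

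Expression is the UMIs of a gene summed over the cells of a group, in CPM, counts scaled to a common total taken without the 392 immunoglobulin genes. Ratios are log2 of SFB-positive over SFB-negative. Genes were named with 20 or more CPM in a group, a log2 ratio of at least 0.58 in size (1.5-fold), an interval that excluded no difference, and all 4 ratios between wells of different pools at least 1.25-fold in the same direction. Ribosomal, mitochondrial, haemoglobin, immunoglobulin and unnamed genes were left out. The 10 highest and 10 lowest were named over all cells, and the 5 highest and 5 lowest in each isotype and state. Up to 5 V genes with the largest differences were named among those at 1% of clones or more. Members of gene lists and cell type markers were given as examples of their list, and other genes singled out were chosen after their values were seen.

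The marker lists were germinal centre, light zone, dark zone, cycling, memory, atypical memory, plasmablast and naive-like B cells, and T cell, myeloid, plasmacytoid dendritic, epithelial, stromal and erythroid cells. The gene lists were TGF-beta and IgA switching, interferon-gamma and T-bet, type I interferon response, T cell help and CD40, antigen receptor activation, MHC class II presentation, class switch and mutation machinery, secretory and unfolded protein response, homing and positioning, toll-like receptors, survival and apoptosis, oxidative phosphorylation, glycolysis, dissociation and stress, and inhibitory receptors with atypical surface genes. A list is given as the median log2 ratio of its members at 5 CPM or more. Members were counted as higher or lower from 1.5-fold between the groups, with all pairs of wells at least 1.25-fold the same way. Each list also has its percentile among 10000 random lists of genes of like expression, which describes size and is no test.

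Antibody counts were turned into centred log-ratios (natural logarithm) over the 7 antibodies. Mutation is the percent of heavy chain V bases that differed from the germline gene. Clones are those of the authors, joined over the wells of a pool. Heavy chains were shared between pools when V gene, J gene and CDR3 amino acids were equal. A reweighted ratio gave both groups the same shares of isotype and state, over 18 strata with at least 20 cells in each group.

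Groups, list members, the naming rule, comparisons and most alternatives were set before the data were examined. The alternatives left out each well in turn, and varied the isotype call, the clustering (resolution 0.5 and 1.5), depth (cells thinned to 1500 UMIs), doublets, totals and size factors, the CPM minimum (5 and 50), the weight of cells, the antibody scale, the mutation summary, the clone definition and the number of cells drawn. The planned mutation alternative from the rearrangement tables was not run, because these hold no identity column, and the authors' mutation count per cell was used in its place. Its definition was not in the files, and it is read here as covering heavy and light chains. Shares and genes under an alternative were judged against counting error. List medians, antibodies and mutation folds were judged against the spread between pairs of wells. Counts of genes named again under another CPM minimum have neither spread, and all were counted as moved. For clone size, V genes and clone sharing, values of the sorted isotypes alone were seen first, and the planned population of all cells was set back afterwards. The gene lists, antibody, light chain and CDR3 values followed under alternatives were picked after their values had been seen, and so was the split of Prg2 in GCB by cluster 5.

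The naming rule was tested on simulated counts with the depth of these wells. Over all cells it named 49 of 71 genes set at 1.5-fold, 66 of 66 at 2-fold and 63 of 63 at 4-fold, and 0 of 3662 genes left unchanged. For the smaller PB population it named 49 of 83 genes at 1.5-fold, 66 of 66 at 2-fold and 51 of 51 at 4-fold, and 1 of 3349 unchanged genes. With the known totals, the intervals covered the true ratio in 95.1% and 95.5% of genes. All genes judged had a mean over the wells of at least 2 times the 20 CPM minimum, 3862 genes over all cells and 3549 for PB. The rates therefore do not cover named genes nearer that minimum, such as Tnfrsf21 and Mt1 over all cells. The simulation held counting error only, with no difference between mice, pools or wells beyond the set folds. It therefore cannot show how often genes would be named between real pools without an effect of SFB.

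Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for size factors only. Gene positions are from the RefSeq annotation of GRCm38.p6.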

Results

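The data compare class-switched B cells of Peyer's patches between mice without SFB (SFB-negative) and mice colonised with SFB (SFB-positive), to ask how colonisation goes with the isotypes, states, transcriptome and receptors of these cells. Each group was 1 pool of 5 mice read in 2 wells. The SFB-negative wells held 6681 and 7321 kept cells with median UMIs of 5926 and 5508 per cell, and the SFB-positive wells held 5549 and 6275 cells with medians of 7596 and 8083. Median genes per cell were 2307 and 2180 against 2558 and 2719. SFB-positive cells were therefore deeper, with group medians of 5701 and 7857 UMIs. Immunoglobulin genes took 2.05% of SFB-negative and 4.93% of SFB-positive UMIs. Differences below are between single pools, so that an effect of SFB and a difference between these pools of mice cannot be separated, and the well values show technical spread only.

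IgA and IgG2b cells made up more of the SFB-positive pool, and IgG1 cells more of the SFB-negative pool. The sorted isotypes had been mixed to a measured ratio, so these shares read that mix. IgA was 25.6% of SFB-negative cells (95% interval 24.9% to 26.3%) and 39.5% of SFB-positive cells (38.6% to 40.4%). IgG1 was 39.7% (38.9% to 40.5%) against 11.05% (10.5% to 11.6%). IgG2b was 9.77% (9.28% to 10.3%) against 35.6% (34.7% to 36.5%). Wells of a pool differed by less than these gaps, with IgG1 at 40.9% and 38.6% in the SFB-negative wells and 11.1% and 10.96% in the SFB-positive wells. Cells whose heavy chain was IgM made up 20.9% and 11.7%, and IgD 4.06% and 2.13%.

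Cell states differed inside each isotype. The largest difference, in IgA cells, involved cluster 3, a mostly follicular-type cluster whose leading genes included the atypical memory markers Fcrl5 and Bhlhe41. Nearly equal numbers of SFB-negative IgA cells were germinal centre B cells (GCB) and cells of cluster 3, whereas SFB-positive IgA cells were mainly GCB. IgG1 and IgG2b cells instead held more plasmablasts (PB) in the SFB-positive pool. GCB made up 48.3% (46.6% to 49.9%) of SFB-negative and 81.3% (80.2% to 82.4%) of SFB-positive IgA cells. Cluster 3 made up 45.6% (43.9% to 47.2%) against 13.6% (12.6% to 14.6%), with wells at 45.4% and 45.8% against 12.3% and 14.8%. PB were 3.71% and 4.67% of IgA cells. Among IgG1 cells PB were 1.55% (1.24% to 1.91%) against 9.34% (7.82% to 11.1%), and GCB 95.5% against 88.4%. Among IgG2b cells PB were 6.80% (5.52% to 8.26%) against 16.4% (15.3% to 17.6%), GCB 74.3% against 72.4% and cluster 3 14.04% against 8.75%.

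**Figure D1:**
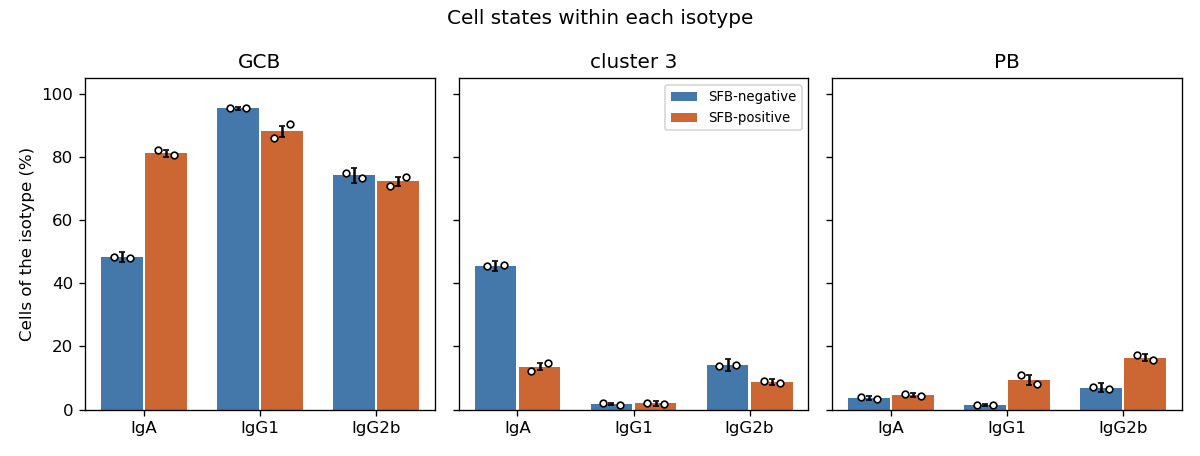
Share of IgA, IgG1 and IgG2b cells (%, vertical axis) that were GCB, cluster 3 or PB, with a bar per pool, error bars for exact 95% Clopper-Pearson intervals and open circles for the 2 wells. Cluster 3 held 45.6% of SFB-negative and 13.6% of SFB-positive IgA cells.

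Over all cells, the state shares also carry the different isotype mix. GCB were 61.6% and 70.9%, the authors' follicular type FOB 35.9% and 20.03%, and PB 2.47% (2.22% to 2.74%; 346 cells) and 9.07% (8.56% to 9.61%; 1073 cells). Cluster 3 was 17.0% (16.3% to 17.6%) and 10.7% (10.1% to 11.3%). Cluster 2, led by Sell and made mostly of IgM and IgD cells (74.0% and 19.98% of it in the SFB-negative pool), was 18.3% and 9.79%. IgG2b cells were 26.9% of SFB-negative and 64.4% of SFB-positive PB, and IgA cells 38.4% and 20.3%. Cluster 5, which overlapped with PB and was led by Prg2 and Jchain, was 3.46% and 11.7%. Cluster 8, with few UMIs and a median mitochondrial share of 6.37%, which can mark damaged cells (1.53% to 2.84% in the other clusters), was 3.91% and 1.45% of all and 7.12% and 1.61% of IgG1 cells, and cluster 9, led by histone genes, 1.27% and 1.77%. Wells of a pool differed in these small clusters, with cluster 9 at 0.419% and 2.05% against 2.16% and 1.42%, so that its direction depended on the well, and SFB-positive cluster 8 at 1.89% and 1.07%.

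Gene expression over all cells was compared next. The 10 genes highest in SFB-positive cells included 3 heat shock genes and 3 genes that led cluster 5, and the 10 lowest included the naive-like markers Ccr7 and Fcer2a. Prg2 (ENSMUSG00000027073, chromosome 2, 84980461 to 84983632), which encodes eosinophil major basic protein and led cluster 5, was at 16.1 CPM in SFB-negative and 183 CPM in SFB-positive cells, a log2 ratio of 3.51 (3.43 to 3.58). With isotype and state shares made equal, the Prg2 ratio was 1.35. Hspa1b (ENSMUSG00000090877, chromosome 17, 34956429 to 34959238), an inducible heat shock protein 70 gene, was at 7.25 and 46.3 CPM, a log2 ratio of 2.67 (2.56 to 2.79), or 2.39 with equal shares. Its neighbour Hspa1a was at 20.6 and 102 CPM with a ratio of 2.31 (2.24 to 2.38), and the cofactor gene Hsph1 had 1.08. The metallothionein gene Mt1 had 2.23 (2.11 to 2.35). Next were Apoc2 at 1.80, Rsph1 at 1.59, Atp1b1 at 1.22, Pcbp1 at 1.14 and Jchain, which encodes the joining chain of secreted IgA and IgM, at 1.06. With equal shares Atp1b1 was at 0.14 and Jchain at 0.35; both led cluster 5.

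Among genes lower in SFB-positive cells, the scaffold gene Tanc2 (ENSMUSG00000053580, chromosome 11, 105589460 to 105929304) had the largest ratio, at 25.2 against 3.30 CPM and a log2 ratio of -2.93 (-3.10 to -2.77). Emp2, a membrane protein gene, was at 94.5 and 28.5 CPM (-1.73) and Lmo7 at 209 and 78.0 CPM (-1.42). Ccr7, the chemokine receptor that draws lymphocytes to T cell zones, was at 314 and 129 CPM (-1.29), and -0.54 with equal shares. Fcer2a, which encodes CD23, had -1.19, the transcription factor genes Nfil3 and Zfp608 -1.21 and -1.20, Tnfrsf21 -1.13, Nr4a3 -1.12 and Fam43a -1.12. With equal shares Tanc2, Emp2 and Lmo7 were at -2.55, -1.62 and -1.29. By sign alone, Tanc2, Emp2, Lmo7, Ccr7, Hspa1a, Hspa1b and Hsph1 went the same way in 7 of 7 isotypes and states examined. These isotypes and states share cells, and Ccr7 was at only -0.08 in IgG1. Mt1 was lower in PB, at -0.24, and went the same way in 6 of 7, as did Nfil3 and Fam43a. Jchain did so in 5 of 7 and Atp1b1 in 4 of 7. Prg2 was highest in PB, at 677 and 3171 CPM there. Cluster 2 and cluster 3 held only 8 and 7, and 1 and 23, Prg2 UMIs, in 0.117% and 0.604%, and 0.0421% and 0.870%, of cells, too few to tell expression there from free RNA or doublets. The median depth of cluster 2 was 2304.5 and 2479 UMIs per cell, and that of cluster 3 was 4794 and 6743.

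**Figure D2:**
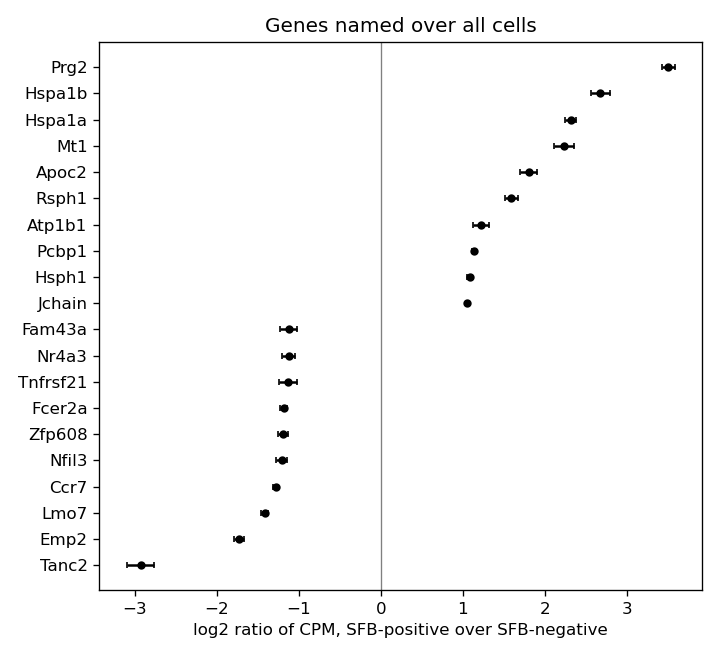
Log2 ratio of CPM, SFB-positive over SFB-negative (horizontal axis), of the 20 genes named over all cells (vertical axis), as points with exact 95% Poisson intervals. Prg2 lies highest at 3.51 and Tanc2 lowest at -2.93.

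Within isotypes, heat shock genes were higher in SFB-positive cells of all 3 sorted isotypes. IgA cells had in addition much lower Il5ra, which encodes the interleukin-5 receptor alpha chain, and IgG1 and IgG2b cells, which held more PB, had higher Prg2. In IgA cells, Il5ra (ENSMUSG00000005364, chromosome 6, 106710375 to 106749037) was at 36.5 CPM in the SFB-negative and 1.63 CPM in the SFB-positive pool, a log2 ratio of -4.48 (-4.85 to -4.14). Camk2n1 had -2.64, the fatty acid carrier Cd36 -2.46, the inhibitory receptor gene Fcrl5 -2.44 and Tbc1d9 -2.36. Fcrl5 and Tbc1d9 led cluster 3, which was the rarer state in SFB-positive IgA cells. Il5ra was also lower inside cluster 3 over all isotypes, at 73.7 against 9.85 CPM (-2.90), or 7.48-fold. The isotype mix differed there, but the IgA share of cluster 3 cells fell only 1.37-fold and the IgG1 share 2.05-fold. This argues against the mix as the whole cause of the Il5ra difference in cluster 3. Higher in SFB-positive IgA cells were Mt1 (2.17), Hspa1b (1.85), Rsph1 (1.77), Hspa1a (1.70) and the histone gene Hist1h2an (1.47). Hist1h2an in IgA cells depended on single wells, at 2.06 without SFB-negative well 2 and 0.80 without SFB-positive well 1. Summed markers of other cell types were also lower in SFB-positive IgA cells, at 27.6 and 14.7 CPM for myeloid cells (-0.91), 47.98 and 29.3 CPM for stromal cells (-0.71), -0.54 for T cells and -0.52 for epithelial cells. RNA from other cells is therefore not excluded for the lower genes such as Cd36.

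IgG1 cells of the SFB-positive pool had Hspa1b at 37.6 against 2.23 CPM (log2 ratio 4.07), Hspa1a at 82.5 against 6.02 CPM (3.78), Prg2 at 89.3 against 7.09 CPM (3.65), the early response gene Jun at 113 against 18.3 CPM (2.62) and Tex14 at 1.63. Lower were Tanc2 (-2.70), Emp2 (-1.76), Chst7 (-1.34), the amino acid oxidase gene Il4i1 (-1.28) and Lmo7 (-1.21). IgG2b cells had Hspa1b at 3.17, Hspa1a and Mt1 at 2.65 each, Prg3 at 2.47 and Prg2 at 2.32. Lower in IgG2b cells were Tanc2 (-3.11), Emp2 (-1.96), Mfge8 (-1.69), Sh2d2a (-1.32) and Ccr7 (-1.27). Summed stromal markers in IgG2b cells were at 60.5 and 31.0 CPM (-0.96), and Mfge8, a gene also of stromal cells and macrophages, was at 35.2 and 17.7 CPM in the SFB-negative wells. Myeloid markers in IgG2b cells were at -0.33. Epithelial markers were higher, at 9.29 and 17.1 CPM (0.88), and so were plasmacytoid dendritic (0.71) and T cell markers (0.58). Leaving out SFB-negative well 2 gave 4.86 for Hspa1b in IgG1, 4.17 for Hspa1b in IgG2b and 3.60 for Prg3 in IgG2b cells, and leaving out SFB-negative well 1 gave 1.85 for the last.

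Within cell states, GCB shared the heat shock, Tanc2 and Emp2 differences of all cells. IgG1 cells made up 61.6% of SFB-negative and 13.8% of SFB-positive GCB, and IgG2b cells 11.8% and 36.3%. The ratios in GCB therefore also carry this isotype mix. PB shared lower Lmo7 and Emp2, and 6 of 13 measured atypical memory markers were higher in cluster 3. In GCB, Hspa1b (3.85), Prg2 (3.60), Hspa1a (3.44), Mt1 (2.46) and Jun (1.61) were higher, and Tanc2 (-3.15), Emp2 (-1.85), Lmo7 (-1.51), Zfp608 (-1.29) and Tnfrsf21 (-1.26) were lower. Of the 2109 Prg2 UMIs in SFB-positive GCB, 1586 were in 273 cells of cluster 5. In GCB outside cluster 5 Prg2 was at 1.41 and 6.37 CPM, with a UMI in 1.03% and 1.96% of cells of median depth 7479 and 8932.5 UMIs, so that free RNA was not excluded there. Prg2 in GCB was 2.15 when the cells with the highest doublet scores were left out, and Hspa1b in GCB was 4.46 without SFB-negative well 2. PB had higher Tmem52 (3.03), Prg3 (2.99), Cox4i2 (2.72), Hist1h2bc (2.34) and Smoc1 (2.30), and lower Nrgn (-3.45), the chemokine gene Ccl5 (-3.43), Il4i1 (-2.87), Lmo7 (-2.61) and Emp2 (-2.53). Some of these depended on single wells. Prg3 in PB was 2.35 without SFB-negative well 1 and 4.01 without SFB-negative well 2, and Hist1h2bc in PB 1.69 and 3.40. Ccl5 in PB was -4.81 without SFB-positive well 1 and -2.68 without SFB-positive well 2, and Nrgn in PB -4.13 without the latter. Summed myeloid markers in PB were at 118 and 72.8 CPM (-0.70) and plasmacytoid dendritic markers at 329 and 418 CPM (0.35), above their levels over all cells. The plasmacytoid dendritic list holds Ccr9 and Bst2, also members of the homing and type I interferon lists, so its sum need not come from other cells. From the myeloid sum, a share of RNA from other cells is not excluded for the named PB genes. The homing list had a median of -0.03 in PB, with 2 of 18 members higher and 5 lower. Its gut homing receptor genes Ccr9 and Ccr10 were at -0.98 and -0.59, and Cxcr3 at 3.81. The PB of both pools differed in isotype, as given above.

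Cluster 3 of the SFB-positive pool had higher Pltp (2.61), Mt1 (2.46), the kinase gene Hck (2.02), Slamf1 (1.99) and Slc22a15 (1.85), and lower Il5ra (-2.90), Lmo7 (-2.22), Dnase1l3 (-1.98), Zbtb18 (-1.89) and Rbm47 (-1.74). IgA cells made up 68.7% of SFB-negative and 50.2% of SFB-positive cluster 3 cells, and IgG2b cells 8.08% and 29.1%. The ratios in cluster 3 therefore also carry this isotype mix. Of 14 atypical memory markers, 13 were measured in cluster 3, with a median log2 ratio of 0.57. By 1.5-fold in all pairs of wells, 6 were higher and 2 lower. Tbx21, which encodes T-bet, was at 1.44 against 12.8 CPM (log2 ratio 3.15, 2.46 to 3.91), Lgals1 at 64.8 against 186 CPM (1.52), Zeb2 at 48.9 against 91.8 CPM (0.91) and Itgax, which encodes CD11c, at 11.9 against 21.8 CPM (0.87). Cd9 (-1.36) and Fcrl5 (-0.60) were lower. The median of this list depended on single wells: it was 0.33 without SFB-negative well 2 and 0.28 without SFB-positive well 2. Cycling genes had a median of 0.58 in cluster 3, with 4 of 10 members higher by 1.5-fold. Markers of other cell types also differed there, with epithelial markers at 51.0 and 8.50 CPM (log2 ratio -2.59) and myeloid markers at 44.2 and 26.1 CPM (-0.76).

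In cluster 2, Hspa1b (2.03), Cfp (1.88), Hspb1 (1.79), Hspa1a (1.49) and B3gnt8 (1.253) were higher. Clu (-3.99), Lyz2 (-3.80), Cxcl13 (-3.42), Mfge8 (-2.14) and Lmo7 (-1.49) were lower. Without SFB-positive well 1, Clu in cluster 2 was at -4.85, Lyz2 in cluster 2 at -3.17 and Cxcl13 in cluster 2 at -4.06. Lyz2 was at -5.06 without SFB-positive well 2. Mfge8 in cluster 2 was at -1.47 and -2.73 without SFB-negative well 1 and 2. Lyz2 is a macrophage gene and Cxcl13 a stromal gene rather than a B cell gene. The summed myeloid markers of cluster 2 were at 31.1 and 6.96 CPM (log2 ratio -2.16) and the stromal markers at 104.7 and 80.4 CPM (-0.38). Both sums include the named genes: Lyz2 held 143 of the 221 SFB-negative myeloid UMIs, and Cxcl13 199 of the 743 stromal UMIs. In the SFB-positive pool these were 5 of 24 and 9 of 277. The sums are therefore not independent of Lyz2 and Cxcl13. Over all cells, summed markers were at 5.38 and 6.03 CPM for T cells, 19.0 and 14.05 CPM for myeloid cells, 48.2 and 59.7 CPM for plasmacytoid dendritic cells, 15.8 and 13.02 CPM for epithelial cells, 48.1 and 32.0 CPM for stromal cells and 2.15 and 1.17 CPM for erythroid cells.

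Gene lists were compared to see which programs differed. Medians of antigen presentation, memory and naive-like genes were below 0 over all cells, and those of plasmablast and secretory genes above 0. By 1.5-fold in all pairs of wells, 2 of 11 antigen presentation, 6 of 12 memory and 5 of 5 naive-like genes were lower, and 5 of 9 plasmablast and 2 of 15 secretory genes were higher. MHC class II genes, which present antigen to T cells, had a median log2 ratio of -0.49 over all cells (11 members, percentile 0 of random lists), with H2-Aa at 3810 and 2567 CPM. The list was also at -0.64 in IgA, -0.40 in IgG1, -0.45 in IgG2b, -0.45 in GCB, -0.59 in PB, -0.30 in cluster 2 and -0.30 in cluster 3. In IgA cells, whose GCB and cluster 3 shares also differed, 9 of 11 members were lower by 1.5-fold. Memory markers were at -0.56 over all cells and -1.25 in IgA cells, where Bcl2 (-1.76), Ccr6 (-1.66), Cd38 (-1.35) and Gpr183 (-1.25) were lower and cluster 3 cells were fewer. Within GCB the memory median was -0.27, and -0.59 for GCB of IgA type with 6 of 11 lower. It was -0.09 in cluster 3, 0.04 in cluster 2, 0.26 in IgG1 cells and 0.12 in GCB of IgG1 type. Naive-like markers were at -1.17 over all cells, -0.85 in GCB and -0.26 in cluster 2.

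Among plasmablast markers, all cells gave a median of 0.68, which was 0.28 with equal isotype and state shares, 1.13 as the mean of per-cell CPM and 0.44 for members at 20 CPM or more. IgG1 cells were at 1.42, IgG2b cells at 0.81 and IgA cells at -0.17. Within GCB of IgG1 and IgG2b type the medians were 0.07 and 0.49. Prdm1, the regulator of plasma cell fate, was at 7.89 and 17.7 CPM over all cells (1.16), and Sdc1, which encodes CD138, at 1.248. Secretory and unfolded protein response genes were at 0.42, 0.57 in IgG1 (0.04 in GCB of IgG1 type), 0.46 in IgG2b, 0.34 in PB and 0.12 in GCB, but at -0.18 in IgA cells with 2 of 15 lower. Dissociation and stress genes were at 0.26 over all cells, with 4 of 13 members higher and 1 lower, 0.39 in GCB, 0.54 in PB and -0.23 in IgA cells, but 0.31 in GCB of IgA type and 0.20 in IgA cells of cluster 3. T cell help and CD40 genes were at -0.30 (Il4ra -0.80, Cd40 -0.01) and -0.60 in IgA cells (-0.33 in GCB of IgA type, -0.25 in IgA cells of cluster 3). Inhibitory receptors and atypical surface genes were at -0.36, homing genes at -0.29, and toll-like receptor genes at -0.35.

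Smaller medians over all cells were those of antigen receptor activation (-0.15, but 0.21 in GCB), light zone (-0.15), TGF-beta and IgA switching (-0.11), type I interferon response (-0.04), class switch and mutation machinery (-0.02), oxidative phosphorylation (0.00), survival and apoptosis (0.02), interferon-gamma and T-bet (0.05), dark zone (0.05), atypical memory (0.07), germinal centre (0.13), glycolysis (0.13) and cycling (0.19). In none of these lists did more than 3 members differ by 1.5-fold one way over all cells. Within IgA cells, list medians also carry the different GCB and cluster 3 shares. TGF-beta and IgA switching genes were at -0.45 in IgA cells, -0.14 in GCB of IgA type and -0.24 in IgA cells of cluster 3, and antigen receptor activation genes at -0.53, -0.19 and -0.10. Germinal centre genes were at 0.37, -0.01 and -0.20. Cycling genes were at 0.47, 0.06 and 0.69.

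Surface antibodies were compared for the differences in state. CD38, which mouse germinal centre B cells lose and memory and naive cells keep, was lower on SFB-positive IgA cells, with a median of 20 UMIs against 7 and a median centred log-ratio of 1.04 against 0.468. Inside one state the difference was small: 0.410 and 0.347 on GCB of IgA type, and 1.67 and 1.66 on IgA cells of cluster 3. CD38 was higher in the SFB-positive pool on PB, with 16 and 30 UMIs (1.12 and 1.63), and also on cluster 2, with 40 and 54 UMIs (1.36 and 1.91), on IgM cells (1.34 and 1.79) and on IgD cells (1.32 and 1.91). IgG1 cells were at 0.312 and 0.392, and IgG2b cells at 0.639 and 0.627. Over all cells IgD was at -0.407 and -0.648, IgM at -0.920 and -1.11 and CD62L at -1.31 and -1.44, with medians of at most 3 UMIs, so that these 3 carry little precision per cell. On cluster 2, IgD had 14 and 11 UMIs.

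Somatic mutation was measured in the heavy chain V gene. IgA cells of the SFB-positive pool were more mutated, and IgG1 and IgG2b cells slightly less. Mean mutation of IgA cells was 1.23% of V bases in the SFB-negative pool (wells 1.24% and 1.22%) and 2.61% in the SFB-positive pool (2.56% and 2.66%). Unmutated chains were 35.3% (33.7% to 36.9%) against 7.41% (6.68% to 8.20%) of IgA cells. The difference was present in GCB of IgA type (1.98% against 2.86%), in IgA cells of cluster 3 (0.499% against 1.59%) and in PB of IgA type (0.608% against 1.44%). IgG1 cells had 2.46% (2.47% and 2.45%) against 2.21% (2.23% and 2.19%), and IgG2b cells 2.05% (2.06% and 2.04%) against 1.93% (1.88% and 1.97%). The IgG2b difference was small, and the median per cell was equal in both pools. IgM cells were at 0.294% and 0.544% and IgD cells at 0.0646% and 0.135%.

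**Figure D3:**
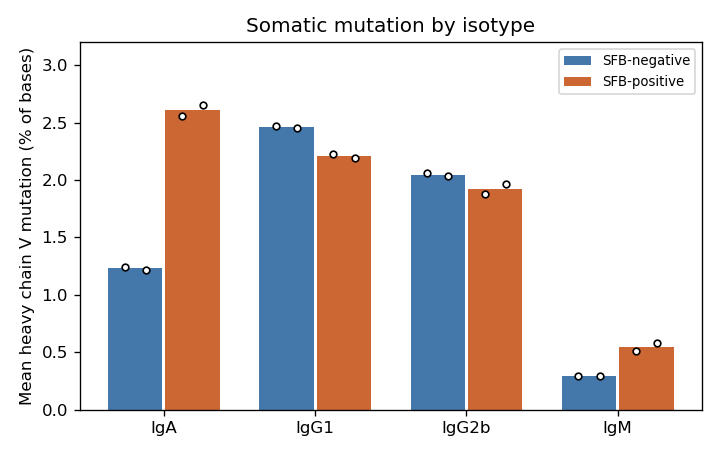
Mean heavy chain V mutation (% of bases, vertical axis) of IgA, IgG1, IgG2b and IgM cells, with a bar per pool and open circles for the 2 wells, and no error bars. IgA cells stood at 1.23% in the SFB-negative and 2.61% in the SFB-positive pool.

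Clonal expansion was compared through the share of cells in clones of 2 or more. Over all cells it was close in both pools, and which was higher depended on the cells and the clone definition. At equal cell number the pools lay further apart within IgG1, IgG2b, PB and cluster 3 cells. With all isotypes it was 46.8% (46.0% to 47.6%) in the SFB-negative and 49.1% (48.2% to 50.02%) in the SFB-positive pool, from 8729 and 7478 clones. When equal numbers of cells were drawn it was 45.4% and 49.1%. Among the sorted isotypes alone it was 59.8% and 55.3%, and with clones defined by V gene, J gene and CDR3 bases the SFB-positive share was lower, by -0.611 points. Leaving out an SFB-positive well also made it lower, with differences of -4.48 and -7.63 points, since fewer cells of a pool leave fewer relatives. The 10 largest clones held 3.91% and 2.99% of cells, and the Shannon index at equal cell number was 8.45 and 8.55. Within isotypes and at equal cell number the share in clones of 2 or more was 49.2% and 53.2% for IgA, 47.8% and 59.2% for IgG1 and 46.9% and 30.01% for IgG2b. With all cells it was 49.2% and 57.0%, 64.5% and 59.2%, and 46.9% and 45.3%. The direction in IgG1 and the size of the difference in IgG2b cells thus depended on cell number. Cluster 3 cells were less often in clones with other cluster 3 cells in the SFB-positive pool, at 21.9% against 9.88% at equal number. PB were likewise less often in clones with other PB, at 24.3% against 8.49%. With all cells the shares were 28.0% and 9.88% for cluster 3, and 24.3% and 18.4% for PB.

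The largest SFB-negative clone used IGHV1-64 and held 79 cells, 75 of them IgG1 and 4 IgA. In the SFB-positive pool 2 clones of 45 cells were largest. One used IGHV3-6 with 29 IgA and 16 IgM cells, and the other used IGHV1-15 with 45 IgG2b cells.

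Heavy chain V genes were compared with each clone counted once. The widest difference was a single gene, IGHV1-47, that was frequent in the SFB-negative pool and rare in the SFB-positive pool. IGHV1-47 (chromosome 12, 114991108 to 114991401) was used by 1005 of 8729 SFB-negative clones, 11.5% (10.9% to 12.2%; wells 11.9% and 11.2%), and 16 of 7478 SFB-positive clones, 0.214% (0.122% to 0.347%; wells 0.170% and 0.254%). Its share was 33.6% against 0.408% of IgG1 clones, 4.32% against 0.112% of IgA clones, 5.81% against 0.283% of IgG2b clones and 2.27% against 0.253% of IgM and IgD clones. The IGHV1-47 cells of the SFB-negative pool, 2418 in number, were GCB in 92.6% of cases, with a mean mutation of 2.27%. Their clones often shared receptor features: IGHJ4 in 84.6%, a CDR3 of 12 amino acids in 63.1% (14.99% of other clones) and the light chain gene IGKV1-110 in 41.9% (6.54% of other clones). IGHV1-72 was used by 5.08% and 2.78% of clones, IGHV1-26 by 3.73% and 5.87%, IGHV3-6 by 2.12% and 4.07% and IGHV1-54 by 0.619% and 2.15%. IGHV1-26 went the other way among IgG2b clones, at 8.43% and 4.28%. By family, IGHV3 held 3.07% and 5.74%, IGHV14 1.59% and 3.52% and IGHV1 62.2% and 60.6%.

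**Figure D4:**
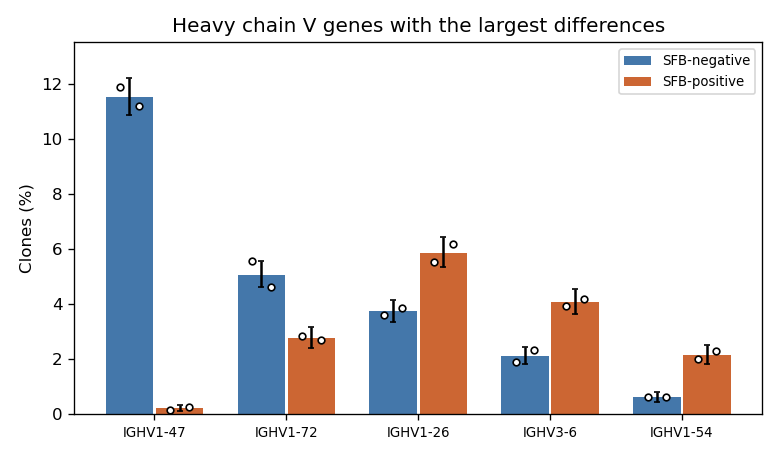
Share of clones (%, vertical axis) that used each of the 5 V genes with the widest differences, with a bar per pool, error bars for exact 95% Clopper-Pearson intervals and open circles for the 2 wells. IGHV1-47 stood at 11.5% of SFB-negative and 0.214% of SFB-positive clones.

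Clones that spanned isotypes or states were compared to ask which cells were related. IgA cells shared clones mostly with IgG1 cells in the SFB-negative pool and with IgG2b cells in the SFB-positive pool, as the mix of isotypes also differed. Of multi-cell clones, 350 of 1279 (27.4%, 24.9% to 29.9%) SFB-negative and 321 of 1461 (22.0%, 19.9% to 24.2%) SFB-positive clones held 2 or more isotypes. The difference in multi-cell clones with 2 or more isotypes, -5.39 points, was -2.42 without SFB-negative well 1 and -2.83 without SFB-negative well 2. Among sorted isotypes alone the shares were 21.0% (18.7% to 23.4%) and 18.4% (16.4% to 20.5%), with overlapping intervals. Clones with IgA and IgG1 cells were 12.98% and 2.67%, those with IgA and IgG2b 5.94% and 11.3%, and those with IgG1 and IgG2b 4.38% and 4.72%. GCB and PB were joined in 5.86% and 12.5% of multi-cell clones, and GCB and cluster 3 in 16.3% and 13.9%. The SFB-positive pool also held more PB and fewer cluster 3 cells. Counted by cell, a GCB cell was in the clone of 33.4% (28.5% to 38.7%) and 22.8% (20.4% to 25.5%) of PB, and of 14.02% (12.6% to 15.5%) and 18.6% (16.5% to 20.8%) of cluster 3 cells, each the other way from the share of clones. Clones of cluster 3 cells alone were 10.1% and 1.98%. Between the pools 15 heavy chains were shared, of 7393 and 6757.

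Light chains and CDR3 lengths were compared last. Lambda light chains were rarer among SFB-positive IgA clones, and the CDR3 of IgG1 clones was longer. Lambda light chains were used by 9.88% (8.64% to 11.2%) of SFB-negative and 6.06% (5.15% to 7.07%) of SFB-positive IgA clones, 3.81% (2.62% to 5.34%) and 2.01% (1.52% to 2.62%) of IgG2b clones, and 1.77% and 1.87% of IgG1 clones. The IgG2b value of the SFB-negative pool differed between its wells, at 4.76% and 2.86%. The mean heavy chain CDR3 of IgG1 clones was 11.3 amino acids in the SFB-negative and 12.2 in the SFB-positive pool, and without IGHV1-47 clones the SFB-negative mean was 11.04. IgA clones were at 11.5 and 11.4, and IgG2b clones at 11.8 in both.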

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

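The tests of reweighting, of handling, of cluster 3, of contig depth within states, of a single clone and of a missing V gene were chosen after the results they address had been seen. Differences between isotypes given here were not tested, since each pool is 1 sample.

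Several measures went one way in IgA cells and the other way in IgG1 or IgG2b cells when each well was taken by itself. Mean mutation was higher in SFB-positive IgA cells by 1.38 points and lower in IgG1 (-0.252) and IgG2b cells (-0.120). The GCB share differed by 33.0 points in IgA and -7.18 points in IgG1 cells. Cells in clones of 2 or more, with clones joined over all isotypes, differed by 6.12 points in IgA, -3.25 in IgG1 and -3.55 in IgG2b cells. That measure depends on cell number: at equal number IgG1 cells were at 47.8% and 59.2%, higher in the SFB-positive pool as in IgA, so the IgG1 direction is not settled. Mean CDR3 length differed by -0.0347 amino acids in IgA and 0.873 in IgG1 clones. The IgA difference has no firm direction, since with each clone counted once per pool the wells overlapped (11.53 and 11.44 against 11.49 and 11.42). Atp1b1, a cluster 5 gene, had log2 ratios of -1.42 in IgA, 2.72 in IgG1 and 1.03 in IgG2b cells.

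The 3 hash features, which no planned comparison used, were counted in all wells, above what a count of 0 allows. Their median UMIs per cell were 45 for Hash1, 277 for Hash2 and 173 for Hash3. Labels do not say what they tag. Hash1 was highest in IgA cells of both pools (90 and 78 UMIs), Hash2 in IgG1 cells (284 and 509) and Hash3, among sorted isotypes, in IgG2b cells (348.5 and 59). Cells were also matched to the median hash profile of each sorted isotype in their well. Nearest to their own profile, taken from these same cells, were 87.6% and 88.5% of IgA, 89.2% and 87.7% of IgG1 and 89.2% and 81.6% of IgG2b cells. IgM and IgD cells of cluster 2 were nearest to the IgG2b profile in 79.0% and 43.3%.

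Heat shock genes (Hspa1a, Hspa1b and Hsph1) were higher in the SFB-positive pool. Among cells of 6000 to 8000 UMIs the median log2 ratio was 2.95, which argues against depth, and with equal isotype and state shares it was 1.99, which argues against the mix of cells. A different handling of one pool, such as a longer time to capture, cannot be told apart from an effect of SFB: the whole dissociation and stress list had a median of 0.26, and each pool was prepared once. Wells of a pool differed by 0.16 and the pools by 2.32. A response to SFB stays open and untested.

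IgA heavy chains were more mutated in the SFB-positive pool. Outside cluster 3 the fold was 1.51, against a well spread of 0.0491, so fewer cluster 3 cells are not the whole cause. It was 2.11 where the constant gene transcript was also IgA (82.2% of IgA cells), which argues against wrong isotype calls, and 1.93 among contigs of 13 to 39 UMIs, where median depth was 21 and 23 UMIs. In GCB of that range, at a median of 23 UMIs in both pools, it was 1.42, against 1.45 in GCB of all ranges and 2.12 in all IgA cells. In cluster 3 of that range it was 3.09 (19 and 22 UMIs), against 3.19 in cluster 3 of all ranges. With each contig UMI value weighted alike, the fold was 2.03 in IgA cells, 1.43 in GCB and 3.08 in cluster 3. This argues against contig depth as the whole cause. A longer or different germinal centre response with SFB may underlie it, as a hypothesis that was not tested, and 1 mouse of the 5 dominating a pool was not testable.

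IGHV1-47 was frequent in the SFB-negative pool. Its largest clone held 2.81% of its cells, which argues against 1 expanded clone, and Cell Ranger's own V calls gave 14.5% against 0.144% of cells, a fold of 100.9, which argues against the V call of 1 tool. Of 19 SFB-positive IGHV1-47 cells 11 carried it unmutated, which argues against the gene missing from every SFB-positive mouse. No germline allele set was at hand, so a strain difference in V genes between some of the mice stays open. Among IgM cells 97 SFB-negative (3.32%) and 4 SFB-positive cells (0.288%) used IGHV1-47, so its difference was not confined to the sorted isotypes. IgM cells as a whole lay mostly in cluster 2 (64.9% and 57.2%). The V gene families IGHV13, with 57 of 8729 SFB-negative and 0 of 7478 SFB-positive clones, and IGHV15, with 0 and 7, bear on this question. They do not settle it. A shared antigen response in the SFB-negative mice may underlie it, as a hypothesis: junctions with RGS as residues 3 to 5 made up 403 of its 1005 clones (40.1%) and 0.479% of others. All its clones together held 662 distinct amino acid junctions. Whether the response came from 1 mouse or several was not testable in a pool.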

How the results depend on the processing

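Alternatives chosen after seeing the data were all barcodes, marker profiles without thinning, the highest doublet scores, list members at 20 CPM or more, leaving out IGHV1-47 or cluster 3, single heavy chain contigs for mutation, the sorted isotypes only and equal draws per group and isotype for clone size. The cause was not tested except where stated. Among 23 main values, 148 comparisons stayed within counting error or well spread, 60 moved beyond it in the same direction and 4 reversed. Among 102 other values the numbers were 815, 156 and 1.

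The reversals concerned cells in clones of 2 or more (2.32 points): -4.47 in sorted isotypes, -0.611 with clones by V, J and CDR3 bases, -4.48 without SFB-positive well 1 and -7.63 without SFB-positive well 2. By construction, fewer cells leave fewer clone members. Equal draws gave 3.74 per group and 0.914 per group and isotype. Also reversed was IGHV1-26 share of clones (2.14 points), at -4.15 among IgG2b clones.

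Without each well in turn, ranges were -29.9 to -27.5 points for the IgG1 share of cells and -33.3 to -30.8 for the cluster 3 share of IgA cells (the isotype, cluster 3 and PB shares followed stayed within counting error, except IgG1). In log2 they were -0.54 to -0.46 for the MHC class II list, all cells, -0.45 to -0.41 for the MHC class II list, GCB, -1.34 to -1.15 for memory markers, IgA, 0.58 to 0.78 for plasmablast markers, all cells, 0.38 to 0.44 for the dissociation and stress list, GCB, -0.90 to -0.78 for the CD38 antibody, IgA cells, log2, and 0.70 to 0.77 for the CD38 antibody, PB cells, log2. The atypical memory markers, cluster 3 (0.57) ranged from 0.28 to 0.72, at 0.33 without SFB-negative well 2 and 0.28 without SFB-positive well 2.

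For receptors the same ranges were 2.08 to 2.16 for mutation of IgA heavy chains, fold, 0.890 to 0.906 for mutation of IgG1 heavy chains, fold, 0.917 to 0.962 for mutation of IgG2b heavy chains, fold, -7.63 to 8.47 points for cells in clones of 2 or more, -12.5 to -11.3 for IGHV1-47 share of clones, -7.63 to -2.42 for multi-cell clones with 2 or more isotypes, -4.00 to -2.95 for lambda share of IgA clones and 0.855 to 0.886 amino acids for CDR3 length of IgG1 clones.

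Isotype from the constant gene gave 15.4 points for the IgA share of cells (13.9), -26.5 for the IgG1 share of cells (-28.7) and 24.5 for the IgG2b share of cells (25.8). All barcodes with a productive heavy chain gave 11.5, -26.0 and 24.5, and cells with 1 heavy contig in Cell Ranger's filtered list (3978 of those left out had 0) gave 27.2 for IgG2b.

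Thinned cells gave -4.50 for the cluster 3 share of all cells (-6.26) and -22.6 for the cluster 3 share of IgA cells (-32.0). The same profiles without thinning gave -4.61 and -25.1, so that profile assignment rather than depth made most of that gap. Clustering at resolution 0.5 and 1.5 gave 8.60 and 8.64 for the PB share of all cells (6.60), and 13.1 and 12.9 for the PB share of IgG2b cells (9.62).

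The MHC class II list, all cells (-0.49) was at -0.53 with the total of all genes and -0.42 with equal isotype and state shares. Memory markers, IgA (-1.25) were at -1.10 and atypical memory markers, cluster 3 at 0.34 for members at 50 CPM or more. Plasmablast markers, all cells (0.68) were at 1.13 as the mean of per-cell CPM, 0.28 with equal shares, and 0.44 and 0.49 for members at 20 and 50 CPM. The dissociation and stress list, GCB (0.39) was at 0.46 as the mean of per-cell CPM and 0.46 for members at 20 CPM.

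CD38 antibody, IgA cells, log2 (-0.83) was at -1.51 as raw UMIs and -1.16 as a share of the antibody total, and CD38 antibody, PB cells, log2 (0.73) at 0.91 and 0.46.

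Mutation of IgA heavy chains, fold (2.12) was 2.44 per clone, 2.37 as a median, 1.92 by the authors' mutation count (as read here) and 1.51 without cluster 3. Mutation of IgG1 heavy chains, fold (0.898) was 0.860 as a median, 0.881 by the authors' count, 0.877 without IGHV1-47 and 0.910 with 1 such contig. Mutation of IgG2b heavy chains, fold (0.942) was 0.973 per clone, 1 (no difference) as a median and 0.875 without cluster 3.

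IGHV1-47 share of clones (-11.3 points) was -17.1 with each cell once, -17.6 in sorted isotypes, -4.20 in IgA, -33.2 in IgG1 and -5.53 in IgG2b clones. CDR3 length of IgG1 clones (0.873) was 0.812 with each cell once and 1.14 without IGHV1-47. Lambda share of IgA clones (-3.82) and multi-cell clones with 2 or more isotypes (-5.39) moved beyond counting error under no other setting.

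With a minimum of 5 or 50 CPM, 6 and 12 of the 20 genes named over all cells were named again. Leaving out cells with 2 or more heavy chains moved 0 of 100 values and leaving out the highest doublet scores 7. TMM and DESeq2 factors moved 1 of 96 each, the mean of per-cell CPM 37 of 96 and equal isotype and state shares 21 of 22. The median gene of PB was at -0.05, and at -0.27 with the total of all genes. Mutation from the rearrangement tables was not run, as these hold no identity. No paired analysis was possible, because each group was 1 pool and replicate numbers are wells of that pool. Of the isotypes and states in which genes were named, PB had the fewest SFB-negative cells (346).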

Other observations

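Cells with an IgM or IgD heavy chain were present although IgA, IgG1 and IgG2b cells had been sorted, at 20.9% and 4.06% of SFB-negative and 11.7% and 2.13% of SFB-positive cells. Most lay in cluster 2, whose mean mutation was 0.114% and 0.211%.

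The V gene family IGHV13 was used by 57 SFB-negative clones (0.653%) and by 0 of 7478 SFB-positive clones, where the exact 95% Clopper-Pearson interval reached 0.0493%. IGHV15 was used by 0 of 8729 SFB-negative clones, with an interval up to 0.0423%, and by 7 SFB-positive clones. The authors' clone names joined 17 clones across the pools, and 879 SFB-negative and 959 SFB-positive clones had cells in both wells of their pool.

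The other antibodies read on these cells had median centred log-ratios over all cells of 0.549 and 0.738 for CD19, 1.87 and 2.04 for CD24 and -0.341 and -0.230 for CD20. Hash2 and Hash3 levels differed between the pools in every isotype, with Hash3 medians of 248 and 26 UMIs on IgA cells.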
